A study of Mus musculus with 12 samples.

How the data were processed

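RNA sequencing of mouse liver was analysed in 12 libraries from 4 groups of 3: wild-type mice given saline, wild-type mice given ENU, Tert-/- mice given saline and Tert-/- mice given ENU. Per the labels' protocols, ENU (N-ethyl-N-nitrosourea, an alkylating mutagen) was injected intraperitoneally at 150 µg per g body weight, the animals were age-matched, and livers were taken 24 h later. The Tert-/- mice were of the G1 generation, per the labels. Total RNA was isolated with TRIzol and libraries were made from 3 µg with the NEBNext Ultra kit, per the labels' protocols. Groups and replicate numbers came from the sample labels. The labels do not state outright that each library came from a separate animal; if any did not, the p-values measure only the spread between these libraries.

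Reads were aligned with HISAT2 and counted with HTSeq against mm10, per the submitters' processing notes; the versions, the annotation release and the strand setting are not given in the sources used here. The authors deposited a single table of FPKM values, which are scaled for gene length and library size, with gene symbols, Ensembl identifiers and positions per the file headers. The table held 49584 genes; 1 further line was emptied before this work, and it and a few genes that met the naming rule are not reported here. Of these identifiers, 49325 occurred in GENCODE M21 and 45128 had the same position there; all coordinates given are those of the table (mm10). There were 95 symbols that occurred more than once, so genes were tracked by identifier. Because the strand setting is not given, reads from overlapping antisense genes cannot be told apart, and members of near-identical families (alpha and beta globins, Cyp4a, Mup and Saa genes) may share reads and are uncertain.

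FPKM values are not counts, so log2(FPKM + 1) values were tested. Genes with at least 1 FPKM in at least 3 of the 12 libraries were kept, which left 12434. A group-means model over all 12 libraries, with a shared spread and no covariate, was fitted with limma 3.58.1 in R 4.3.3 using a mean-variance trend. The contrasts were ENU against saline in each genotype, Tert-/- against wild type in each treatment, the difference between the ENU effects, and the genotype effect averaged over treatments. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all tested genes within each contrast, and the threshold was an adjusted p of 0.05. Fold changes are differences of log2(FPKM + 1), which understate the change of genes with low values. FPKM values are means ± SD over 3 libraries.

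There were 43 gene lists fixed beforehand (pathways, cell type markers and controls), of which 35 had at least 5 tested members. These were compared with all other genes by camera at a preset correlation of 0.01, adjusted over the lists within each contrast; an estimated correlation was an alternative. The rotation test fry, also planned, asked whether the members of a list moved on balance, which does not compare them with other genes. For each list, members were also adjusted over the list alone. Named genes followed a rule: Tert; for each contrast of a pair of groups, the 10 largest increases and decreases past the threshold with no overlap between the 3 and 3 libraries, at least 1 FPKM in the higher group and a curated symbol; for the averaged genotype effect, the 5 largest each way; and, within a list, up to 4 members past the threshold with the largest moderated statistic or otherwise the 2 most abundant. Any other gene is named as chosen after its values were seen. The groups, lists, tests, naming rule and the settings listed first in the last paragraph were set before the data were examined.

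Depth was recovered from the FPKM values. With the mean annotated transcript length (22396 genes) or the smallest whole-number length that fitted (4127 genes), 26523 of 26524 expressed genes gave whole reads within 0.01 in every library. The recovered totals were 30053822 to 43680374 reads per library. The same reads served for an alternative test with limma's voom, with library totals multiplied by median-ratio factors. No pair among the 12 same-group pairs of libraries was as close as counting noise (chi-square per gene at least 41.8), so each library was counted once. Spread between libraries, not read depth, sets the errors given.

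The steps were tested on simulated data, drawn from each gene's mean and spread within groups, with 200 of 12434 genes changed. Reads for voom were drawn from a negative binomial distribution with the same dispersion for all genes. The simulated genes were independent of each other and equally spread in every library. The real libraries were not alike in spread, so the shares and false calls below need not hold for them. For ENU in wild-type mice, 47% of genes changed by 1 and 89% of genes changed by 2 on the log2 scale were recovered, with 7 false calls among 143. For Tert-/- against wild type in ENU the shares were 47% and 91%, with 6 false calls among 144. With no gene changed there were 0 calls by limma in either. The self-test for voom recovered 25% and 92% in the former contrast and 10% and 90% in the latter.

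Alternative settings were a pseudocount of 0.1, no filter, a filter on a mean FPKM of 5, quantile normalization, median-ratio rescaling, no trend, array quality weights, the replicate number as a block, the compared groups fitted alone, and leaving out each replicate. Chosen after seeing the data were leaving out each library for the correlation and the share near Tert, leaving out Tert-/- saline replicate 2 also in the contrasts whose groups do not hold it, voom on the recovered reads, and a clock covariate (the log2 ratio of Dbp to Arntl in each library, with 1 FPKM added to each). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, exact tests and plots.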

Results

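Liver transcriptomes of wild-type mice and of mice lacking Tert, the catalytic subunit of telomerase, were compared 24 h after an injection of ENU or saline, with 3 libraries in each of 4 groups. Between 30053822 and 43680374 reads per library were counted in genes. Between 19576 and 20310 genes had reads in 11 of the libraries, and 17486 in Tert-/- saline replicate 2. That library stood apart in other ways. Its 20 most abundant genes took 29.53% of its reads, against 17.36 to 21.69% elsewhere, and its median ratio to the geometric mean library was 0.649. Within the deposited scaling, the median log2 fold change of all genes was 0.24 for ENU in Tert-/- mice, -0.19 for genotype in saline, -0.11 for genotype averaged over treatments and 0.10 for ENU in wild-type mice. After median-ratio rescaling these medians were 0, -0.01, -0.002 and 0.

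Tert transcripts (chromosome 13, 73627001 to 73649041, mm10) had lower values in each Tert-/- library than in every wild-type library of the same treatment. In saline, Tert was at 3.18, 3.223 and 1.61 FPKM in wild-type replicates 1 to 3 and at 0.443, 0.304 and 0.734 FPKM in the Tert-/- replicates. After ENU, it was at 6.225, 5.694 and 4.705 FPKM in wild type and at 1.625, 1.231 and 1.11 FPKM in Tert-/-. These values rested on 241 to 797 reads per wild-type library and 33 to 201 per Tert-/- library. Reads were thus assigned to the gene in every knockout library. Averaged over treatments, the log2 difference between Tert-/- and wild type was -1.38 (SE 0.15, adjusted p = 0.00417 by limma), and in saline it was -1.27 (SE 0.21, adjusted p = 0.0163). After ENU the log2 difference was -1.49 (SE 0.21), with an adjusted p of 0.175, as no gene passed in that contrast. Group means were 2.67 ± 0.92 FPKM in wild-type saline and 5.54 ± 0.77 in wild-type ENU, a log2 difference of 0.86 (SE 0.21, adjusted p = 0.0953; 0.0232 without Tert-/- saline replicate 2). The means were 0.49 ± 0.22 and 1.32 ± 0.27 FPKM in Tert-/- saline and ENU (log2 difference 0.64, SE 0.21, adjusted p = 0.0764).

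**Figure D1:**
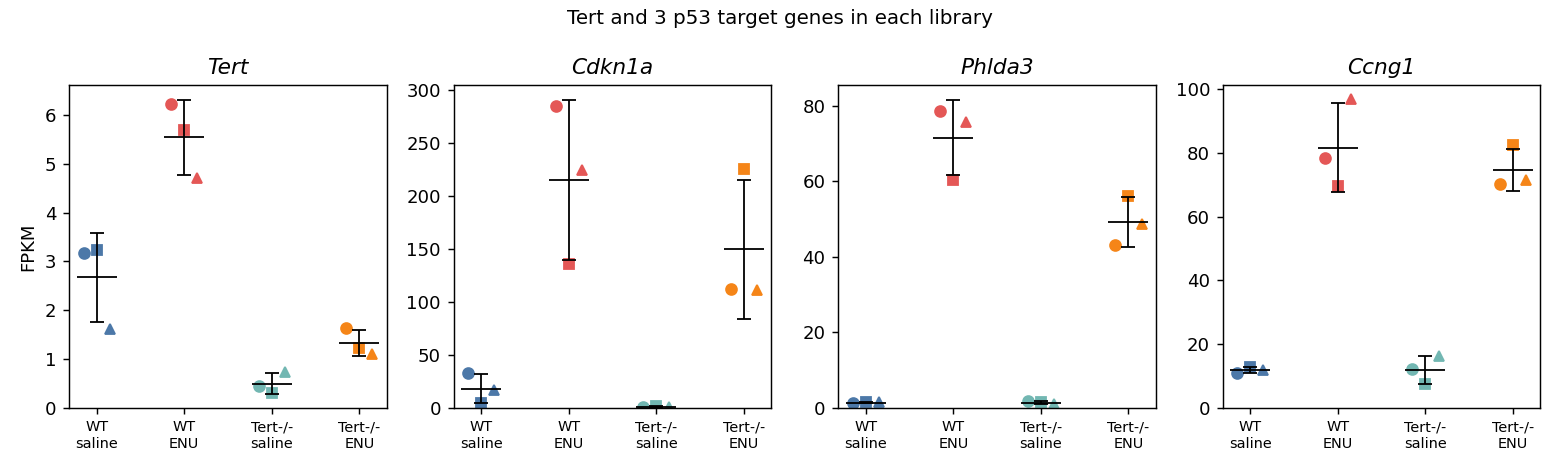
Expression in FPKM (vertical axes) of Tert, Cdkn1a, Phlda3 and Ccng1 in each of the 12 libraries by group; circles, squares and triangles are replicates 1, 2 and 3, and bars are the mean and SD of 3 libraries. Phlda3 lies at 1.37 ± 0.17 and 1.40 ± 0.49 FPKM in the saline groups and at 71.6 ± 9.92 and 49.3 ± 6.60 FPKM in the ENU groups.

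The contrast of ENU with saline in wild-type mice asks how normal liver responded to DNA alkylation. Targets of the tumour suppressor p53 led the response. Phlda3, a repressor of Akt signalling, rose from 1.37 ± 0.17 to 71.6 ± 9.92 FPKM (SD, n = 3; log2 fold change 4.93, SE 0.19, adjusted p = 1.07e-07). Cdkn1a, which encodes a cyclin-dependent kinase inhibitor, rose from 18.1 ± 13.9 to 215 ± 75.3 FPKM (log2 3.77, SE 0.53, adjusted p = 0.00426). Ccng1, the gene of cyclin G1, rose from 11.9 ± 1.01 to 81.6 ± 14.0 FPKM (log2 2.67, SE 0.23, adjusted p = 0.000131). Of 35 tested p53 targets, 13 rose and 0 fell by limma, and 22 rose and 0 fell when adjusted over the list alone; 33 of the 35 estimates were above 0 (camera adjusted p = 5.66e-24). Of these, 21 rose without Tert-/- saline replicate 2, which is in neither group, and 23 over the list alone. This was the only list in any contrast whose call held with an estimated correlation (adjusted p = 0.0368 with an estimated correlation), and it no longer did without Tert-/- saline replicate 2 (adjusted p = 0.126 with an estimated correlation).

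Other wild-type increases included Eda2r, a receptor of the tumour necrosis factor family (log2 2.84, SE 0.19), the apoptosis-enhancing nuclease Aen (log2 2.47, SE 0.25), Psrc1, a microtubule regulator (log2 2.38, SE 0.20), and Ddias, a suppressor of damage-induced apoptosis (log2 2.46, SE 0.25). The glutamate receptor gene Gria3 rose from 0.11 ± 0.07 to 5.80 ± 1.32 FPKM. The lincRNA RP24-286J21.7 (chromosome 8, 121833247 to 121841178) rose from 3.37 ± 1.71 to 177 FPKM (log2 5.38, SE 0.58, adjusted p = 0.000562). Immp2l, a mitochondrial inner membrane peptidase gene (chromosome 12, 41024090 to 41955588), fell from 34.6 ± 2.31 to 5.18 ± 2.46 FPKM (log2 -2.60, SE 0.27, adjusted p = 0.000528). Fhit, at a common fragile site (chromosome 14, 9550092 to 11162035), fell from 3.00 ± 1.32 to 0.14 ± 0.06 FPKM (log2 -1.76, SE 0.22, adjusted p = 0.00166). Among other genes, the actin regulator Carmil1 fell by 2.21 on the log2 scale (SE 0.38), the nicotinic receptor gene Chrna4 by 2.90 (SE 0.32) and the ephrin gene Efna3 by 1.70 (SE 0.24).

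Acacb, an acetyl-CoA carboxylase gene that restrains fatty acid oxidation, fell from 25.3 ± 4.48 to 4.77 ± 0.55 FPKM (log2 -2.18, SE 0.34, adjusted p = 0.00852). It was the only fatty acid synthesis gene to pass among 17 tested, all 17 of which had estimates below 0; 3 fell when adjusted over the list alone (camera adjusted p = 1.02e-09, and adjusted p = 0.367 with an estimated correlation). The count was 4 without Tert-/- saline replicate 2, and 9 over the list alone. The cytochrome P450 gene Cyp2c29 fell from 821 to 325 FPKM (log2 -1.36, SE 0.26), and the deiodinase gene Dio1, which activates thyroid hormone, from 125 ± 23.6 to 42.4 ± 8.48 FPKM (log2 -1.54, SE 0.32). The lipid-binding protein gene Fabp7 fell by 1.41 (SE 0.27) and the beta globin gene Hbb-bt by 2.36 (SE 0.49, adjusted p = 0.0483); neither passed by voom (adjusted p = 0.0543 and 0.132). Hbb-bt was the only call among 7 erythroid markers. When adjusted over the list alone, 1 of them rose and 3 fell, and the median was -1.53 (camera adjusted p = 0.00741, and adjusted p = 0.367 with an estimated correlation). The camera call of this list was lost with voom. Among erythroid markers 1 rose and 3 fell without Tert-/- saline replicate 2, and 2 and 4 over the list alone.

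MHC class II genes and markers of endothelial and Kupffer cells had estimates mostly below 0 after ENU in wild type. For 8 MHC class II genes the median log2 fold change was -0.90, with 0 calls by limma and 5 lower when adjusted over the list alone (camera adjusted p = 2.58e-08, and adjusted p = 0.332 with an estimated correlation). H2-Ab1 was at -1.18 (SE 0.37) and Cd74 at -1.10 (SE 0.44). For 14 sinusoidal endothelial markers the median was -0.63, with 0 calls and 3 lower when adjusted over the list alone (camera adjusted p = 3.49e-09, and adjusted p = 0.332 with an estimated correlation). Clec4g was at -0.67 (SE 0.28). The 14 Kupffer cell markers had a median of -0.43 and 0 calls on either adjustment (camera adjusted p = 4.47e-05, and adjusted p = 0.444 with an estimated correlation). Without wild-type ENU replicate 3 this call was lost (camera adjusted p = 0.0672). All 15 heat shock genes had estimates above 0, with a median of 0.65, 0 calls and 4 higher when adjusted over the list alone (camera adjusted p = 2.33e-05, and adjusted p = 0.367 with an estimated correlation). Hspa8 was at 0.65 (SE 0.21). The 28 genes of PPARalpha targets and fatty acid oxidation had a median of 0.45, 0 calls, and 7 higher when adjusted over the list alone (camera adjusted p = 0.00098, and adjusted p = 0.444 with an estimated correlation). The calls without Tert-/- saline replicate 2 were 4 of 8 lower for MHC class II (8 over the list alone), 6 of 14 lower for endothelial markers (10), 0 of 14 for Kupffer cell markers (0), 4 of 15 higher for heat shock genes (11) and 8 of 28 higher for PPARalpha targets (11, with 1 lower). The log2 ratio of Dbp to Arntl, which peak at opposite times of day, was -2.117, 0.136 and -1.807 in the saline libraries and -0.521, 4.148 and 4.173 in the ENU libraries. Genes that peak with Dbp had a median log2 fold change of 1.73 and genes that peak with Arntl a median of -0.89. The ratio lay above all saline libraries in ENU replicates 2 and 3 but not in replicate 1. An ENU effect and a different clock phase at sampling were therefore not fully separated in this contrast.

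In all, 93 genes rose and 31 fell after ENU in wild-type mice among 12434 tested by limma. That was 75% of the calls higher, against 59.2% after quantile normalization (103 higher, 71 lower) and 56.2% after median-ratio rescaling (68 higher, 53 lower). Of the calls, 77 that rose and 28 that fell had no overlap between the 3 ENU and 3 saline libraries and met the naming rule. Chance alone parts 3 from 3 libraries in 10% of genes. The count was 1324 without Tert-/- saline replicate 2, which is in neither group but adds to the shared spread, and all 124 calls were among them. It was 49, 56 and 71 without wild-type saline replicates 1, 2 and 3, 79 and 50 without wild-type ENU replicates 2 and 3, 1111 when the 2 groups were fitted alone and 28 with a clock covariate.

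In Tert-/- mice, the same contrast asks whether livers without telomerase responded to ENU, and p53 targets were again among the largest increases. Cdkn1a rose from 1.17 ± 0.25 to 149 ± 65.7 FPKM (log2 6.04, SE 0.53, adjusted p = 0.000169) and Phlda3 from 1.40 ± 0.49 to 49.3 ± 6.60 FPKM (log2 4.40, SE 0.19, adjusted p = 3.9e-07). Of 35 p53 targets, 19 rose and 0 fell, and 22 rose and 0 fell when adjusted over the list alone (camera adjusted p = 1.1e-08, and adjusted p = 0.273 with an estimated correlation). The counts were 21 and 1 without Tert-/- saline replicate 2. Eda2r rose by 2.63 (SE 0.19), Ccng1 by 2.60 (SE 0.23), Aen by 2.51 (SE 0.25) and RP24-286J21.7 by 3.73 (SE 0.58) on the log2 scale. The receptor genes Notch1 and Epha2 rose by 2.61 (SE 0.40) and 2.53 (SE 0.50), and the chromatin gene Gse1 by 2.46 (SE 0.48). Without Tert-/- saline replicate 2 the increases of Notch1, Epha2 and Gse1 were 2.02, 1.99 and 1.71, and that of RP24-286J21.7 was 3.14.

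Genes of fatty acid oxidation rose in Tert-/- livers. Of 28 PPARalpha targets and fatty acid oxidation genes, 17 rose and 0 fell, and 23 rose and 1 fell when adjusted over the list alone (median 1.004; camera adjusted p = 1.51e-06, and adjusted p = 0.395 with an estimated correlation). They included the thioesterase gene Acot1 (log2 2.04, SE 0.30, adjusted p = 0.0043), the lipid droplet gene Plin2 (log2 1.40, SE 0.22) and the mitochondrial fatty acid import genes Cpt2 (log2 0.80, SE 0.13) and Slc25a20 (log2 0.89, SE 0.17), the last 2 of which did not pass by voom (adjusted p = 0.129 and 0.0893). The fatty acid hydroxylase gene Cyp4a14 rose from 4.71 ± 5.67 to 111 ± 82.2 FPKM (log2 4.45, SE 1.15, adjusted p = 0.034), which became 0.0546 without Tert-/- saline replicate 2 and 0.0849 by voom. Lipogenic genes fell: Thrsp, a regulator of lipid synthesis, from 1132 ± 599 to 110 ± 71.4 FPKM (log2 -3.55, SE 0.64, adjusted p = 0.00872), and the acetyl-CoA synthetase gene Acss2 by 1.24 (SE 0.31). These were the 2 of 17 fatty acid synthesis genes that passed on either adjustment (median -0.58; camera adjusted p = 1.21e-05, and adjusted p = 0.484 with an estimated correlation), and 9 fell without Tert-/- saline replicate 2 (13 over the list alone; median -1.24).

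Globin transcripts fell in Tert-/- livers after ENU. Hba-a1 went from 109 ± 117 to 6.27 ± 3.51 FPKM and Hbb-bs from 218 ± 193 to 18.5 ± 12.7 FPKM (log2 -3.47, SE 0.64, and -3.29, SE 0.58). The log2 fold changes of Hba-a2 and Hbb-bt were -2.77 (SE 0.73) and -3.01 (SE 0.49). Without Tert-/- saline replicate 2 the log2 fold changes of Hba-a1, Hbb-bs, Hba-a2 and Hbb-bt were -2.62, -2.6, -1.82 and -2.51. These 4 were all the calls among 7 erythroid markers on either adjustment (median -2.77, or -1.82 without Tert-/- saline replicate 2; camera adjusted p = 0.000363, and adjusted p = 0.273 with an estimated correlation). Immp2l fell from 65.3 ± 13.2 to 6.22 ± 1.71 FPKM (log2 -3.21, SE 0.27, adjusted p = 0.000166) and Fhit from 4.18 ± 0.57 to 0.03 ± 0.05 FPKM (log2 -2.33, SE 0.22). Hamp2, a paralogue of the iron hormone gene Hamp, fell by 3.51 (SE 0.78), and the lipid-binding protein gene Fabp5 fell by 2.77 (SE 0.58). The urinary protein gene Mup15 fell by 2.49 (SE 0.57). The Tert-/- saline means of Hamp2 (51.5 ± 74.0 FPKM), Fabp5 (25.2 ± 28.6 FPKM), Hba-a1 (109 ± 117 FPKM) and Hba-a2 (15.2 ± 18.4 FPKM) had an SD above the mean. Of 8 MHC class II genes 0 rose and 2 fell, H2-Aa by 1.71 (SE 0.41) and H2-Eb1 by 1.37 (SE 0.39), and 5 fell when adjusted over the list alone (camera adjusted p = 1.91e-06, and adjusted p = 0.395 with an estimated correlation). Of these genes 1 fell without Tert-/- saline replicate 2, and 1 over the list alone; H2-Eb1 did not pass (adjusted p = 0.075). Of 23 hepatocyte identity genes 2 rose and 2 fell, and 2 and 4 over the list alone, among them the transcription factor gene Cebpa (log2 0.72), the urea cycle gene Ass1 and the transthyretin gene Ttr (log2 -1.03 and -0.81). Of that list 1 rose and 5 fell without Tert-/- saline replicate 2 (2 and 5 over the list alone), and Cebpa did not pass (adjusted p = 0.058). Hba-a2 (adjusted p = 0.141), Hamp2 (0.075), H2-Aa (0.0539), H2-Eb1 (0.0744) and Cebpa (0.219) did not pass by voom. The hepatocyte identity median was -0.28, or -0.16 without Tert-/- saline replicate 2, and its direction turned under quantile normalization (camera adjusted p = 0.000992, against 0.944, and adjusted p = 0.273 with an estimated correlation).

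Altogether 1011 genes rose and 180 fell after ENU in Tert-/- mice, 84.9% of the calls higher, against 57% after quantile normalization (638 higher, 482 lower) and 59.7% after median-ratio rescaling (518 higher, 350 lower). Without Tert-/- saline replicate 2, 1608 rose and 522 fell. The log2 fold changes had a Spearman rho of 0.356 with transcript length, and of 0.086 without that library. The count of 1191 was 2130 and 2795 without Tert-/- saline replicates 2 and 3, 266, 437 and 402 without Tert-/- ENU replicates 1 to 3, 769 by voom, 356 with a clock covariate and 56 when the 2 groups were fitted alone.

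**Figure D2:**
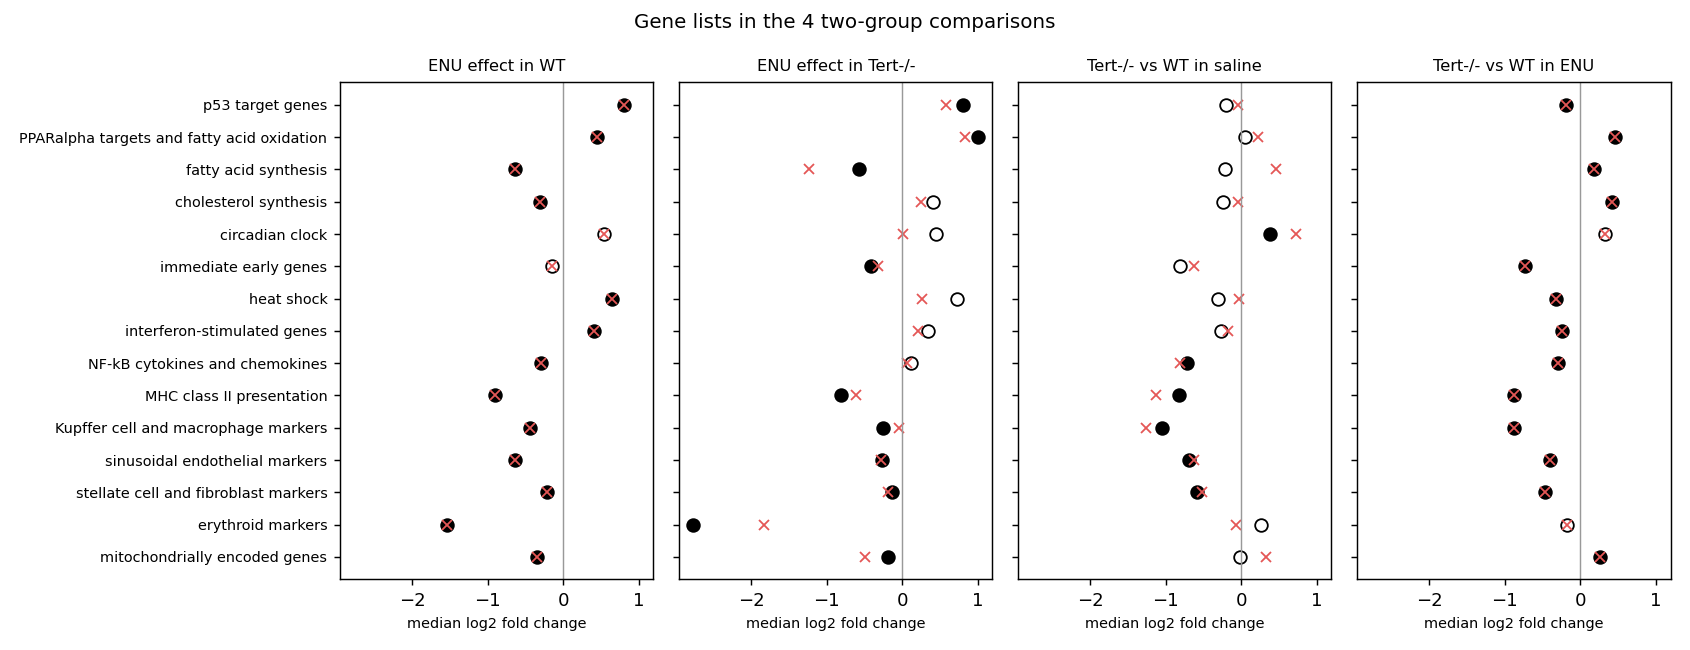
Median log2 fold change (horizontal axis) of 15 gene lists in the 4 contrasts of a pair of groups; filled circles passed camera at an adjusted p of 0.05, open circles did not, and red crosses are the medians without Tert-/- saline replicate 2. The p53 target median is 0.80 for ENU in both genotypes, and 0.59 in Tert-/- without that library.

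The ENU effects in both genotypes were compared gene by gene to ask whether loss of Tert altered the response. Across 12434 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.569 and a Spearman rho of 0.508. The genotypes shared 77 genes that rose, against 7.56 for independent lists, and 18 that fell, against 0.45; 0 genes were called in opposite directions. The genotypes shared 580 that rose and 112 that fell without Tert-/- saline replicate 2, against 137.47 and 10.96 for independent lists, with 8 called in opposite directions. No saline or ENU library was common to both effects. Both were nevertheless tested with the same estimate of each gene's spread, so the numbers for independent lists can be too low. The test of the difference itself called 0 genes by limma and 0 by voom, with 844 and 884 at an unadjusted p under 0.05. Acot1 and Plin2 were the only PPARalpha targets that passed when adjusted over the list alone (interaction log2 1.72 and 1.16). Both were picked after their values were seen, and neither passed without Tert-/- ENU replicate 2. The 28 PPARalpha targets had a median interaction of 0.60 (25 above 0; camera adjusted p = 0.00601), and the 22 cholesterol synthesis genes a median of 0.55 (22 above 0; camera adjusted p = 0.0135), both with adjusted p = 0.927 with an estimated correlation. Without Tert-/- saline replicate 2 these medians were 0.29 and 0.49 (camera adjusted p = 0.00494 and 0.0136), and 0 PPARalpha targets passed over the list alone. The PPARalpha call was lost without Tert-/- ENU replicate 2 (0.0579). The cholesterol call was lost without wild-type ENU replicate 3 (0.154), Tert-/- saline replicate 3 (0.368) or Tert-/- ENU replicate 3 (0.158). Among cholesterol synthesis genes, the interaction was 0.55 (SE 0.53) for Insig1.

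In saline, Tert-/- against wild type compares the genotypes without ENU, and clock genes were among the largest changes. Dbp, a clock output factor, was at 78.4 ± 11.2 FPKM in Tert-/- and 4.01 ± 4.04 in wild type (log2 4.26, SE 0.74, adjusted p = 0.0174). Arntl, a core clock activator, was at 0.55 ± 0.25 against 8.89 ± 0.96 FPKM (log2 -2.68, SE 0.40, adjusted p = 0.0154). The clock repressor Ciart was higher by 3.40 (SE 0.57), or by 4.11 without Tert-/- saline replicate 2. The activator Npas2 was lower by a log2 of -2.22 (SE 0.43, adjusted p = 0.0588 by voom). Of 18 clock genes 2 were higher and 2 lower, and 5 and 4 when adjusted over the list alone (median 0.37; camera adjusted p = 0.0199, and adjusted p = 0.677 with an estimated correlation). There were 8 higher and 3 lower without Tert-/- saline replicate 2 (9 and 4 over the list alone; median 0.73), and the call was lost without replicate 3 of that group (camera adjusted p = 0.163). The log2 ratio of Dbp to Arntl was 5.256, 6.051 and 5.745 in the Tert-/- saline libraries and -2.117, 0.136 and -1.807 in the wild-type ones. The ratio parts these groups completely, so loss of Tert and a different clock phase at sampling cannot be told apart in this contrast.

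**Figure D3:**
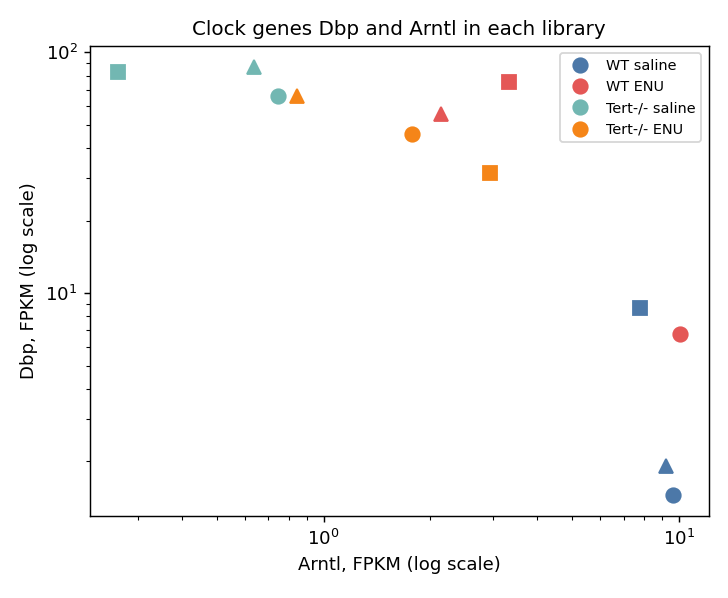
Dbp against Arntl in FPKM (both axes logarithmic) in each of the 12 libraries, coloured by group, with circles, squares and triangles for replicates 1, 2 and 3. The 3 wild-type saline libraries and wild-type ENU replicate 1 have log2 ratios of Dbp to Arntl from -2.117 to 0.136, and the 8 others from 3.05 to 6.051.

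The limit on clock phase holds for every gene in this contrast, as the ratio of Dbp to Arntl parts its groups. Further genes higher in Tert-/- saline livers were the deubiquitinase gene Usp2 (log2 2.95, SE 0.55), the uridine phosphorylase gene Upp2 (2.23, SE 0.55), the cytochrome P450 gene Cyp2a5 (1.79, SE 0.44), the glutaredoxin gene Glrx (1.52, SE 0.25), Gpcpd1, which acts in choline metabolism (1.42, SE 0.31), and the respiratory chain gene Ndufa12 (1.35, SE 0.23). The chemokine gene Ccl22 was at 2.23 ± 0.16 against 0.13 ± 0.04 FPKM (log2 1.51, SE 0.23, adjusted p = 0.0154; 0.0858 by voom), and H2-Bl at 3.65 ± 1.18 against 0.62 ± 0.43. Among the genes that were lower, Cdkn1a was at 1.17 ± 0.25 against 18.1 ± 13.9 FPKM (log2 -2.80, SE 0.53, adjusted p = 0.0215; 0.0703 by voom). The choline kinase gene Chka (log2 -2.48, SE 0.43), the tubulin gene Tubb2a (-2.55, SE 0.38), the chloride channel family gene Clic3 (-2.34, SE 0.37), Abtb2 (-2.06, SE 0.23), the transcriptional co-repressor gene Irf2bp2 (-2.03, SE 0.40) and the homeobox gene Pitx3 (-3.22, SE 0.83; adjusted p = 0.0949 by voom) were lower too. The mitochondrial ATP synthase gene mt-Atp8 was at 3.85 ± 2.65 against 16.3 ± 4.49 FPKM (log2 -2.00, SE 0.39; -1.43 without Tert-/- saline replicate 2). The 15 mitochondrially encoded genes did not fall as a list. Their median was -0.016, with 1 higher and 1 lower (camera adjusted p = 0.131), and it was 0.325 without Tert-/- saline replicate 2.

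Some markers of resident non-hepatocyte cells were lower in Tert-/- saline livers. Of 14 sinusoidal endothelial markers 0 were higher and 4 lower: the cadherin gene Cdh5 (log2 -1.34, SE 0.24, adjusted p = 0.0174), Stab1 (-0.76, SE 0.17), Pecam1 (-0.82, SE 0.19) and Oit3 (-0.80, SE 0.19). When adjusted over the list alone 8 were lower (camera adjusted p = 0.000843, and adjusted p = 0.677 with an estimated correlation). Of 5 cholangiocyte markers, all with estimates below 0 (median -0.35), 0 passed by limma and 1 was lower over the list alone (camera adjusted p = 0.246). Of 14 Kupffer cell markers, Adgre1 was lower (-1.22, SE 0.31) and 9 were when adjusted over the list alone, with a median of -1.05 (camera adjusted p = 0.00119, and adjusted p = 0.677 with an estimated correlation). Of 14 stellate cell markers, Reln and Hgf were lower (-1.11 and -0.98), 6 over the list alone (camera adjusted p = 0.0027, and adjusted p = 0.677 with an estimated correlation). Of 15 NF-kB cytokines and chemokines, Ccl2, Vcam1 and Nfkbia were lower (-1.54, -1.07 and -0.99), 6 over the list alone (camera adjusted p = 0.0027, and adjusted p = 0.677 with an estimated correlation). Of 8 MHC class II genes, H2-DMb1 was lower (-0.93, SE 0.21), 4 over the list alone (median -0.82; camera adjusted p = 0.0199, and adjusted p = 0.677 with an estimated correlation). Of 17 bile acid genes, the bile acid uptake transporter gene Slc10a1 was higher (0.67, SE 0.14; camera adjusted p = 0.0199, and adjusted p = 0.677 with an estimated correlation). Stab1 (adjusted p = 0.169), Pecam1 (0.0701), Oit3 (0.0834), Adgre1 (0.0942), Hgf (0.0738), Nfkbia (0.0524) and H2-DMb1 (0.0864) did not pass by voom. The calls without Tert-/- saline replicate 2 were 6 endothelial (10 over the list alone), 7 Kupffer (12), 5 stellate (8), 4 NF-kB (9) and 5 MHC class II genes (7) lower and 5 bile acid genes (6) higher. The hepatocyte identity and cytochrome P450 lists were called higher by camera (adjusted p = 0.0309 and 0.0457, and adjusted p = 0.677 and 0.678 with an estimated correlation), and both turned direction under quantile normalization. Without Tert-/- saline replicate 2 the adjusted p of these lists was 0.512 and 0.266. They were also lost without Tert-/- saline replicate 3 (0.15 and 0.265), the former without wild-type saline replicate 1 (0.07) and the latter without replicate 2 of that group (0.164). Without Tert-/- saline replicate 3 the Kupffer (0.15), NF-kB (0.179), MHC class II (0.449) and bile acid (0.174) calls were lost as well. The MHC class II call was also lost without Tert-/- saline replicate 1 (0.1), and the bile acid call without wild-type saline replicate 2 (0.129; its median of 0.21 was 0.33 without Tert-/- saline replicate 2).

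In saline, 93 genes were higher and 530 lower in Tert-/- mice, 14.9% of the calls higher, against 36.9% after quantile normalization (181 higher, 309 lower) and 29.9% after median-ratio rescaling (126 higher, 295 lower). Without Tert-/- saline replicate 2, 582 were higher and 1020 lower. The log2 fold changes had a Spearman rho of -0.404 with transcript length, and of -0.105 without that library. The count of 623 depended on single libraries. It was 4, 54 and 16 without wild-type saline replicates 1, 2 and 3, 1602 and 1451 without Tert-/- saline replicates 2 and 3, 329 by voom, 1 when the 2 groups were fitted alone and 0 with a clock covariate, which differs with the groups.

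After ENU, Tert-/- against wild type asks whether the genotypes differed once exposed, and no single gene passed: limma called 0 genes of 12434 and voom 0, with 541 and 593 at an unadjusted p under 0.05. Without Tert-/- saline replicate 2 there were 0, with 1309 at an unadjusted p under 0.05; fitted alone, the 2 groups gave 1. Lists differed by camera. All 28 PPARalpha targets had estimates above 0 (median 0.46; 2 higher when adjusted over the list alone; camera adjusted p = 1.33e-20, and adjusted p = 0.0889 with an estimated correlation). Fabp1, the liver fatty acid binding protein gene, was at 0.54 (SE 0.33). All 22 cholesterol synthesis genes were above 0 (median 0.42; 0 on either adjustment; camera adjusted p = 6.56e-09, and adjusted p = 0.335 with an estimated correlation). All 16 immediate early genes were below 0 (median -0.73; 4 lower when adjusted over the list alone; camera adjusted p = 3.08e-13, and adjusted p = 0.0889 with an estimated correlation). Junb, a component of the AP-1 transcription factor, was at 29.66, 35.18 and 57.28 FPKM in Tert-/- and 194.8, 124.8 and 222.9 FPKM in wild type (log2 -2.14, SE 0.34, adjusted p = 0.175). The members that passed over the list alone without Tert-/- saline replicate 2 were 8 PPARalpha targets, 0 cholesterol synthesis genes and 4 immediate early genes.

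The same cell type markers had estimates mostly below 0 after ENU. Kupffer cell markers had a median of -0.88 (14 of 14 below 0; camera adjusted p = 7.67e-11, and adjusted p = 0.255 with an estimated correlation). Clec4f was at -0.86 (SE 0.36) and C1qa at -0.92 (SE 0.41). MHC class II genes had a median of -0.88 (3 of 8 lower when adjusted over the list alone; camera adjusted p = 1.58e-08, and adjusted p = 0.247 with an estimated correlation). Stellate markers had a median of -0.48 (camera adjusted p = 1.26e-09, and adjusted p = 0.151 with an estimated correlation) and endothelial markers of -0.41 (camera adjusted p = 1.52e-06, and adjusted p = 0.255 with an estimated correlation), with 0 of 14 members passing on either adjustment in each. The 38 interferon-stimulated genes had a median of -0.25 (0 on either adjustment; camera adjusted p = 3.14e-06, and adjusted p = 0.356 with an estimated correlation), which was lost without Tert-/- ENU replicate 2 (camera adjusted p = 0.0644). The 35 p53 targets had a median of -0.19, and 3 were lower when adjusted over the list alone (camera adjusted p = 1.52e-05, and adjusted p = 0.255 with an estimated correlation). The members lower over the list alone without Tert-/- saline replicate 2 were 8 of 14 Kupffer, 7 of 8 MHC class II, 9 of 14 stellate, 0 of 14 endothelial, 0 of 38 interferon-stimulated and 3 of 35 p53 target genes, with 0 calls by limma over all genes in each. The log2 ratio of Dbp to Arntl was 4.08, 3.05 and 5.186 in Tert-/- ENU libraries and -0.521, 4.148 and 4.173 in wild-type ones.

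Averaged over treatments, Klf2, a shear stress-responsive transcription factor gene, was at 3.96 ± 1.53 and 5.49 ± 0.55 FPKM in Tert-/- saline and ENU against 16.3 ± 4.25 and 13.8 ± 4.36 in wild type (log2 -1.48, SE 0.20, adjusted p = 0.0155). Zfp36l1, which promotes mRNA decay, was lower by a log2 of -1.42 (SE 0.22, adjusted p = 0.0184), the proteoglycan gene Sdc3 by -1.60 (SE 0.24), Irf2bp2 by -1.54 (SE 0.29) and Abtb2 by -1.40 (SE 0.16, adjusted p = 0.00712). Glrx was higher by 1.37 (SE 0.17, adjusted p = 0.00981), the sulfotransferase gene Sult1b1 by 0.72 (SE 0.13), the mitochondrial import gene Timm8a1 by 0.64 (SE 0.12), Smim4 by 0.62 (SE 0.14) and Crcp by 0.60 (SE 0.11). Of 16 immediate early genes 7 were lower and 0 higher, 9 over the list alone. They included Junb (-1.29, SE 0.24), Zfp36 (-1.09, SE 0.23) and Klf4 (-0.67, SE 0.14; camera adjusted p = 1.38e-05, and adjusted p = 0.36 with an estimated correlation). Of 14 Kupffer cell markers 5 were lower and 13 over the list alone, including Adgre1 (-1.08, SE 0.22) and Csf1r (-0.97, SE 0.22; camera adjusted p = 4.47e-07, and adjusted p = 0.454 with an estimated correlation). Of 14 endothelial markers 3 were lower and 10 over the list alone (camera adjusted p = 2.62e-06, and adjusted p = 0.36 with an estimated correlation), and of 14 stellate markers 3 and 11 (camera adjusted p = 2.43e-06, and adjusted p = 0.36 with an estimated correlation). Smim4 (adjusted p = 0.0935), Junb (0.0518) and Csf1r (0.0984) did not pass by voom. In the fit without Tert-/- saline replicate 2, 7 immediate early genes (8 over the list alone), 11 Kupffer (13), 8 endothelial (13) and 8 stellate markers (11) were lower.

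The averaged effect called 32 genes higher and 421 lower, 7.1% of the calls higher, against 24.7% after quantile normalization (68 higher, 207 lower) and 20.9% after median-ratio rescaling (45 higher, 170 lower). Without Tert-/- saline replicate 2, 483 were higher and 1141 lower. The log2 fold changes had a Spearman rho of -0.357 with transcript length, and of -0.118 without that library. The 453 calls were 8, 37 and 96 without wild-type saline replicates 1 to 3, 17 and 9 without wild-type ENU replicates 1 and 2, 9, 19 and 9 without Tert-/- ENU replicates 1 to 3, 1624 without Tert-/- saline replicate 2, 303 by voom and 0 with a clock covariate. All wild-type saline libraries and wild-type ENU replicate 1 had lower ratios of Dbp to Arntl than every Tert-/- library. Genotype and clock phase at sampling were therefore not fully separated in the averaged effect either. Calls near Tert were counted because the strain label names mixed strains, and a targeted allele can carry flanking donor-strain DNA. Within 10 Mb of Tert, 1 of 69 tested genes was called, Glrx, against 451 of 12364 elsewhere (two-sided Fisher's exact test, p = 0.521). Within 20 Mb it was 4 of 163: Fgfr4, Glrx, Hk3 and Tgfbi (Fisher's exact p = 0.531). A test of shares cannot decide whether Glrx itself (chromosome 13, 75839868 to 75850151) differed through flanking DNA or through loss of Tert. Genes within 10 Mb made up 0.22% of the calls. Where leaving out a library left few calls, that share was 14.29% (without wild-type saline replicate 1, Fisher's exact p = 0.0382) or 12.5% (without wild-type ENU replicate 2, Tert-/- ENU replicate 1 or Tert-/- ENU replicate 3, Fisher's exact p = 0.0436 each). These fits left only 8 or 9 calls, so each share rests on very few genes. The p-values were not adjusted for leaving out each library in turn.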

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

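The gene lists below were fixed beforehand, and their test of the difference and the re-fits without Tert-/- saline replicate 2 were planned. The test of the difference between the ENU effects in Tert-/- and wild-type mice called 2 lists by camera, both higher in Tert-/-. For 28 PPARalpha targets and fatty acid oxidation genes the median difference was 0.60, with 25 of 28 above 0, and it was 0.29 without that library. For 22 cholesterol synthesis genes the median difference was 0.55, with 22 of 22 above 0, and 0.49 without it. Neither list passed with an estimated correlation (adjusted p = 0.927 for each). By fry, which asks whether a list moved and not whether it differed from other genes, neither passed (adjusted p = 0.9 for each).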

How the results depend on the processing

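Leaving out Tert-/- saline replicate 2 in the contrasts whose groups do not hold it, voom, the clock covariate, and leaving out libraries for the correlation and for the share near Tert were chosen only after the results were seen. Most counts moved with single libraries, and the cause was not tested. Across the left-out libraries the counts of genes by limma ran from 49 to 1324 for ENU in wild type, 266 to 2795 for ENU in Tert-/-, 4 to 1602 for genotype in saline and 8 to 1624 for the averaged genotype effect. Counts of lists ran from 11 to 18, 3 to 12 and 2 to 15 for ENU in Tert-/-, genotype in saline and the interaction. The correlation of the ENU effects in both genotypes ran from 0.51 to 0.591. The share of averaged calls within 10 Mb of Tert, 0.22%, ran from 0.15 to 14.29%, the latter without wild-type saline replicate 1, and was 12.5% without wild-type ENU replicate 2, Tert-/- ENU replicate 1 or Tert-/- ENU replicate 3. The shares of 14.29% and 12.5% came from fits with very few calls. Without a filter the gene counts were 729, 280 and 95 for ENU in Tert-/-, genotype in saline and the average. With a mean FPKM of at least 5 they were 69 for ENU in wild type, 393 for genotype in saline and 179 for the average. The average gave 275 genes after quantile normalization and 215 after median-ratio rescaling. By voom there were 769 genes for ENU in Tert-/- and 329 for genotype in saline. The replicate numbers were not used as pairs, because 7 of 18 same-number pairs had a correlation above 0.1 (-0.156 to 0.208), although 8 of 12 libraries were closest to one of their own number. As a block they gave 344 genes for genotype in saline (against 623), 267 for the average (against 453) and 6 lists for the interaction. A batch shared by libraries of the same number is therefore not excluded. Fitted alone, the groups gave 1111 genes for ENU in wild type, 56 for ENU in Tert-/-, 1 for genotype in saline and 1 for genotype after ENU. Array quality weights gave 2531, 7075, 6725, 136, 1520 and 5133 genes for ENU in wild type, ENU in Tert-/-, genotype in saline, genotype after ENU, the interaction and the average, but the weights did not converge.

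The clock covariate is confounded with the groups. With it, 28, 356, 0 and 0 genes were called for ENU in wild type, ENU in Tert-/-, genotype in saline and the average, and 6, 14 and 10 lists for genotype in saline, the interaction and the average. In saline the log2 difference became 1.65 for Pitx3 and 0.23 for Npas2, and acute phase proteins turned direction for ENU in wild type (camera adjusted p = 0.0711). For Dbp it became -0.39, but Dbp is part of the covariate, so its value cannot count as a check. The interaction gave 6 lists with a pseudocount of 0.1 and 4 with no filter. Genotype in saline gave 16 lists with no filter, 5 with a mean FPKM of at least 5 and 6 with array quality weights. ENU in Tert-/- gave 9 lists with quantile normalization and 9 with array quality weights. Hepatocyte identity turned direction with quantile normalization for ENU in Tert-/- (adjusted p = 0.944) and for genotype in saline (0.62, and 0.949 with array quality weights), and so did cytochrome P450 genes for genotype in saline (0.951). With an estimated correlation 1, 0, 0, 0, 0 and 0 lists were called for ENU in wild type, ENU in Tert-/-, genotype in saline, genotype after ENU, the interaction and the average, all against the other genes. By fry, which asks whether a list moved and not whether it differed from other genes, they were 1, 3, 3, 0, 0 and 9.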

Other observations

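Several gene groups not described above held changes after ENU in Tert-/- mice. Among 38 interferon-stimulated genes, Stat2 (log2 0.92, SE 0.21), Zbp1 (1.23, SE 0.30), Irf9 (1.01, SE 0.27) and Dtx3l (adjusted p = 0.0391) rose and Cxcl9 fell by 1.59 (SE 0.43), without a camera call (adjusted p = 0.857). Of these, 7 rose and 0 fell without Tert-/- saline replicate 2, as Cxcl9 did not pass (adjusted p = 0.0604). Of 15 nucleic acid sensing genes 3 rose: Adar, which edits double-stranded RNA, by 0.83, Dhx58 by 0.72 and Ikbke by 0.57 (camera adjusted p = 0.721). Of 16 MHC class I genes, the transactivator gene Nlrc5 and the peptide transporter gene Tap1 rose by 0.95 and 0.98 (camera adjusted p = 0.721). Of 25 NRF2 and glutathione genes 4 rose, among them Gclc, the rate-limiting enzyme of glutathione synthesis (1.23, SE 0.29; camera adjusted p = 0.409). Zbp1 (adjusted p = 0.0744), Cxcl9 (0.0603), Dhx58 (0.224) and Ikbke (0.336) did not pass by voom. Among 19 retroelement silencing factors, the cytidine deaminase gene Apobec3 was lower in Tert-/- mice in saline (log2 -0.61, SE 0.15, adjusted p = 0.0426; 0.119 by voom), without a camera call (adjusted p = 0.11). Of these factors, 1 was higher and 2 were lower without Tert-/- saline replicate 2.

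The acute phase gene Lcn2, picked after its values were seen, differed widely within groups. It was at 591.7, 415 and 46.6 FPKM in wild-type saline replicates 1 to 3 and at 1269, 533 and 130.4 in wild-type ENU. In Tert-/- mice it was at 169.1, 119 and 70.55 FPKM in saline and at 140.1, 1895 and 142.3 after ENU. Its values fell from replicate 1 to replicate 3 in every group except Tert-/- ENU. The repair gene Mgmt, which removes alkyl groups from guanine and was also picked after its values were seen, was at 5.408, 4.98 and 5.893 FPKM in wild-type saline and at 10.78, 9.693 and 9.794 in wild-type ENU (adjusted p = 0.0844).

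The tests of read number and of group mates without it for the library that stood apart, of matched depth for long loci and of the clock genes were chosen only after the results were seen. Tert-/- saline replicate 2 stood apart from the other 11 libraries, and no biological explanation was tested. Fewer sequenced reads were argued against, since a library with a lower total had 2090 more genes with reads. Loss of long transcripts stays open: its log2 ratios to its group mates had a Spearman rho of -0.475 with transcript length, against -0.144 for the lowest of the others (-0.271 with it left out of its mates' averages). The same ratios had a rho of 0.415 with GC content and of -0.405 with locus length. Transcript length was not separated from these for this library. The first test could not decide whether a few abundant genes took more of its reads. Its spread was 1.10 before and 1.20 after rescaling, but dividing a library by a constant factor hardly alters its spread. The spread after rescaling was 1.48 times the highest of the others, under the bound of 1.5. That highest value was from Tert-/- saline replicate 3, whose mates included the doubted library. With the doubted library left out of its mates' averages the ratio was 2.76, which argued against those genes as the whole cause.

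In wild type, genes with the longest loci had lower values after ENU (median log2 fold change -0.43 in the longest bin of 99 genes, 83.8% below 0; -0.10 in the next bin of 300 genes, 63.7% below 0; 0.05 in the bin of 900 genes below it; rank correlation with locus length -0.071), a pattern found on these data. In Tert-/- mice the longest bin was at -0.08 (-0.31 without Tert-/- saline replicate 2), the next bin of 300 genes at 0.18 with 37% below 0 (-0.10 without it), and the rank correlation with locus length at 0.198 (-0.069 without it; partial 0.021, and -0.076 without it). Transcript length, GC content and expression level were argued against as the whole cause in wild type, where the partial rank correlation given them was -0.119. The doubted library is in neither wild-type group, whose libraries parted by -0.158. Depth was argued against, but only by 2 pairs of ENU and saline libraries of matched depth, which differed by -0.277 and -0.256. The exact permutation p was 0.1 in wild type, the smallest that 3 against 3 libraries can give, 0.4 in Tert-/- mice and 0.02 over both genotypes (adjusted p = 0.06).

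Clock genes differed between Tert-/- and wild-type mice in saline, with log2 ratios of Dbp to Arntl from 5.256 to 6.051 against -2.117 to 0.136. The doubted library was argued against, as the lower of the other Tert-/- saline libraries lay 5.12 above the highest wild-type saline library. The genotype and a different clock phase at sampling cannot be told apart. The 2 wild-type ENU libraries within the range of the 6 Tert-/- libraries decide nothing, because ENU could itself shift the clock. The median of genes that peak with Dbp lay 2.93 above that of genes that peak with Arntl, which either explanation would give.

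Other splits of the libraries were tested for chance. With 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real counts were 124 for ENU in wild type, 1191 for ENU in Tert-/- and 623 for genotype in saline, each reached in 1 of 10 splits, with 1 as the highest other. For the average, 1 of 100 splits reached 453, the real one, and the highest other was 353. That argues against chance without excluding it, as another split came near and the count moved with single libraries. The splits do not part the genotype from the clock phase. For genotype after ENU the real count by limma was 0 (541 at an unadjusted p under 0.05, and 0 by voom), and for the interaction it was 0 by limma too (844 at an unadjusted p under 0.05, and 0 by voom). Every split reaches a count of 0 (10 of 10 with 0 as the highest other, and 100 of 100 with 9), so these splits say nothing about chance.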
